A study of Mus musculus with 2 samples.

How the data were processed

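Cells of the colonic lamina propria of male C57BL/6 mice were profiled with the 10x Single Cell 3' kit V3, per the labels, in 1 library labelled wild type and 1 labelled lncly6c-deficient. The values are UMI counts per gene and barcode as deposited, with no normalization, made with Cell Ranger and STAR 2.5.1b on mm10 according to the submitters' processing notes and with software version 3.0.2 per the file headers. The matrices hold 31053 genes and only barcodes with at least 500 UMIs. Groups were taken from the titles and genotype labels, which are alike, although the file names carry the opposite genotype words. The libraries held 3020 and 6133 barcodes, given here and below as wild-type-labelled then deficient-labelled, with medians of 4426.5 and 7539 UMIs, and 7 barcode sequences were present in both.

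Barcodes with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept, which left 2610 and 5890; the mitochondrial limit alone was exceeded by 408 (13.5%) and 232 (3.78%). Scrublet, run per library in scanpy 1.11.5 with an expected rate of 5%, marked 6 and 2 cells, or 0.0941% of all, so it removed almost no doublets. Removal by score rank, of 0.8% of cells per 1000 cells (54 and 278 cells), was therefore added as an alternative. The 8492 cells kept were scaled to 10000 UMIs and log-transformed. The 2000 genes with the largest dispersion within 20 bins of mean expression, among genes seen in at least 10 cells, were standardized over both libraries and limited to 10 standard deviations. From 30 principal components, a graph of 15 neighbours weighted by shared neighbours was clustered with leidenalg 0.10.2 at resolution 1, without batch correction. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

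Each of the 29 clusters was scored against markers of 25 cell types fixed before the data were examined. The score of a type was the mean log2 fold of its markers against all other cells, with 0.1 added to both means, counting markers found in at least 10% of the cluster's cells with a log2 fold above 0.5. A cluster took the name of its best type if at least 3 markers passed, if no other type had more markers among its 10 leading genes (found in at least 25% of cells), and, for clusters with under 1/3 of the library's median depth, if a marker was among these 10. A monocyte-like cluster also needed raised Ly6c2. These thresholds and the Ly6c2 requirement were set after the data were seen. They named 25 clusters and left 4 unnamed, and every name ends in "-like" because it rests on RNA alone.

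With 1 library per group and no replicates, no test was run, and cells were not used as replicates. Shares of cells carry exact Clopper-Pearson 95% intervals. UMIs were summed over a class and given as CPM with exact Poisson intervals, and ratios as log2 of CPM, deficient-labelled over wild-type-labelled, with the exact conditional binomial interval. A count of 0 was set at a floor of 3 counts. Genes with at least 50 UMIs over both libraries were measured, and classes with at least 100 cells in each library were compared. The share of cells with a Ly6c2 UMI was taken after thinning each cell to 1000 UMIs at random.

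The 21 gene lists were fixed before the data were examined, and 2 listed genes, Ly6a2 and Mx2, were not in the matrix. They were Ly6C-high monocyte, mature gut macrophage, Ly6C-low monocyte and Nr4a1 axis, MHC class II, MHC class I, inflammatory cytokine and chemokine, regulatory and alternative activation, interferon-stimulated, immediate-early and dissociation, lysosome and phagocytosis, glycolysis, oxidative phosphorylation, butyrate receptor and transport, proliferation, T helper and cytotoxic, B cell maturation, immunoglobulin, epithelial secreted and antimicrobial, stromal matrix, erythrocyte and mitochondrially encoded genes. A list with at least 3 measured members was given a median log2 ratio and its percentile among medians of 10000 random lists of as many genes, matched on expression in 20 bins. The size of 1.5-fold used to count members, and the bootstrap over members (2000 draws) that gives the wide interval of a list median, were chosen after the data were seen.

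Genes were named by a rule fixed before the data were examined. In monocyte-like and macrophage-like cells these were lncly6c, Nr4a1, Cebpb, Ly6c2, Ccr2, Adgre1, Cx3cr1 and H2-Ab1, up to 4 members of each described list with the largest ratios, and the 10 highest and 10 lowest genes with at least 100 UMIs, leaving out immunoglobulin and T cell receptor segments, mitochondrial and ribosomal protein genes and unnamed predicted genes. The value of 1 gene that the rule names is not reported. In other classes up to 2 members per list and 3 genes on each side were taken. Genes that lead a cluster, genes of a cluster shown by library, and genes on the same side in every class were chosen after their values were seen.

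Counting intervals and list percentiles were tested on simulated Poisson counts with 8743 genes, at a depth near that of the monocyte-like and macrophage-like comparison. Gene proportions were those of all deposited barcodes. The simulation held no spread between cells or between libraries. It therefore checks the calculation, not whether the intervals hold for these data. Intervals covered the true ratio in 95.4% of 8543 unchanged genes, 88.7% of 71 genes planted at 1.5-fold, 93.9% of 66 at 2-fold and 96.8% of 63 at 4-fold. Estimates past 1.5-fold were 0.960%, 53.5%, 95.5% and 100% of these. An unchanged list of 15 genes had a median of 0.04 at percentile 84.95 and a raised one a median of 0.55 at percentile 100.

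Alternatives fixed before the data were examined were a stricter cell filter (500 genes, 1000 UMIs, 10% mitochondrial), doublets kept, resolutions 0.5 and 2, genes centred within each library, clustering without the monocyte and macrophage list genes, thinning to 2000 UMIs or none, other CPM totals, ratios centred on the median gene, means over cells, minimums of 10 and 200 UMIs, and each class alone. Added later were the score-rank doublets, the unnamed Retnla and Ace clusters counted as macrophage-like, leaving out monocyte-like cluster 23 or macrophage-like cluster 27, equal weights of both classes, the same interferon-stimulated genes with and without cluster 23, and the same settings for each named gene.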

Results

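Single cells from the colonic lamina propria, the connective tissue layer under the gut epithelium that holds most intestinal macrophages, were profiled by droplet single-cell RNA sequencing from male C57BL/6 mice. One library was labelled wild type and one was labelled lncly6c-deficient, with the whole gene of the long noncoding RNA lncly6c deleted by CRISPR. They are called here the wild-type-labelled and the deficient-labelled library. The names of the deposited files carry the opposite genotype words from the labels, and with those words every direction given here would be exchanged. The wild-type-labelled library held 3020 barcodes and 23384895 unique molecular identifier (UMI) counts, and the deficient-labelled library held 6133 barcodes and 54773076 UMIs. After filtering, 2604 and 5888 cells remained, with medians of 6205 and 7847.5 UMIs per cell. Each group was 1 library with no replicates, so the intervals given cover counting error only, no test between groups was possible, and a difference between the libraries is not thereby a difference between genotypes.

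The deleted gene itself was not detected in either library. No UMI of lncly6c, annotated as 1700016P04Rik (ENSMUSG00000101894), was counted in the wild-type-labelled or in the deficient-labelled library. The annotation places this lincRNA on chromosome 6 of mm10, from 13413337 to 13415996 on the plus strand, with exon 1 from 13413337 to 13413550 and exon 2 from 13415782 to 13415996. A count of 0 allows cells with a UMI to make up at most 0.0993% of the 3020 and 0.0489% of the 6133 barcodes, which does not limit the cells that expressed the gene. Among monocyte-like and macrophage-like cells the limit was 0.515% of 582 and 0.182% of 1649 cells. The gene therefore gave no check on which library lacked it. Among the neighbouring genes, Tmem168 had a counts-per-million value (CPM) of 23.1 in the wild-type-labelled and 30.05 in the deficient-labelled library. Bmt2 had 24.0 and 24.1 CPM, Gpr85 had 11.7 and 10.2, and Tmem106b had 13.4 and 17.7, in the same order of libraries. Thsd7a differed more, at 0.397 and 1.84 CPM from 9 and 100 UMIs. These values are over all cells kept, and the mix of cell classes differed between the libraries.

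The share of each cell class among the cells shows which populations each library held, and the series asks about macrophage differentiation. Neutrophil-like cells were 10.6% (95% exact Clopper-Pearson interval 9.48 to 11.9) of the wild-type-labelled library and 2.5% (2.11 to 2.93) of the deficient-labelled library. Macrophage-like cells were 11.4% (10.2 to 12.6) against 16.5% (15.5 to 17.4). B cell-like, T cell-like, plasma cell-like and fibroblast-like cells were also larger shares of the deficient-labelled library. Shares of Ly6c-high monocyte-like cells, 11.0% (9.81 to 12.2) and 11.5% (10.7 to 12.4), and of conventional dendritic cell-like cells, 31.5% (29.7 to 33.3) and 32.8% (31.6 to 34.0), lay close together. Within the dendritic cell-like class, however, cluster 7, led by Xcr1, was 3.73% (3.03 to 4.53) and 6.32% (5.71 to 6.97). Its clusters 6, 12 and 14 were also larger in the deficient-labelled library and clusters 1, 8 and 20 smaller, all with overlapping intervals.

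B cell-like cells were 3.26% (2.62 to 4.02) of the wild-type-labelled and 9.99% (9.23 to 10.8) of the deficient-labelled library. T cell-like cells were 3.92% (3.20 to 4.73) and 6.76% (6.13 to 7.43). Most of this gap lay in cluster 15, at 0.576% (0.323 to 0.948) and 2.75% (2.35 to 3.20), of which doublet score rank removed 29.4% of cells. The other T cell-like clusters, 13 at 2.15% and 2.38% and 19 at 1.19% and 1.63%, had overlapping intervals. Fibroblast-like cells were 0.845% (0.530 to 1.28) and 4.99% (4.45 to 5.58), and antibody-secreting plasma cell-like cells were 0.192% (0.0624 to 0.448) and 1.09% (0.838 to 1.39). Goblet cell-like cells, which secrete mucus, were 0.845% (0.530 to 1.28) and 0.442% (0.289 to 0.646). Natural killer or type 1 innate lymphoid-like cells were 1.57% (1.13 to 2.13) and 2.06% (1.71 to 2.45). The shares of ILC2-like cells, 0.422% and 0.476%, and of ILC3-like cells, 0.230% and 0.340%, had overlapping intervals. The order of the libraries was the same in all 8 settings tried, the reported one included, for every class but the Ly6c-high monocyte-like one, which was larger in the deficient-labelled library in 6 settings and in the wild-type-labelled library in 2.

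Unnamed cells made up 24.3% (22.6 to 26.0) of the wild-type-labelled and 10.6% (9.81 to 11.4) of the deficient-labelled library, in 4 clusters. The largest, led by Serpinb2 and the eosinophil chemokine receptor gene Ccr3, held 16.1% and 4.13% of the cells and had a median of 853 UMIs per cell. A second, led by the unnamed loci Gm26917 and Gm42418, held 3.73% and 2.60%. The next, led by Retnla and the lipoprotein lipase gene Lpl, held 2.42% and 3.09%. The last, led by Ace and Treml4, genes of Ly6C-low monocytes, held 2.04% and 0.764%.

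**Figure D1:**
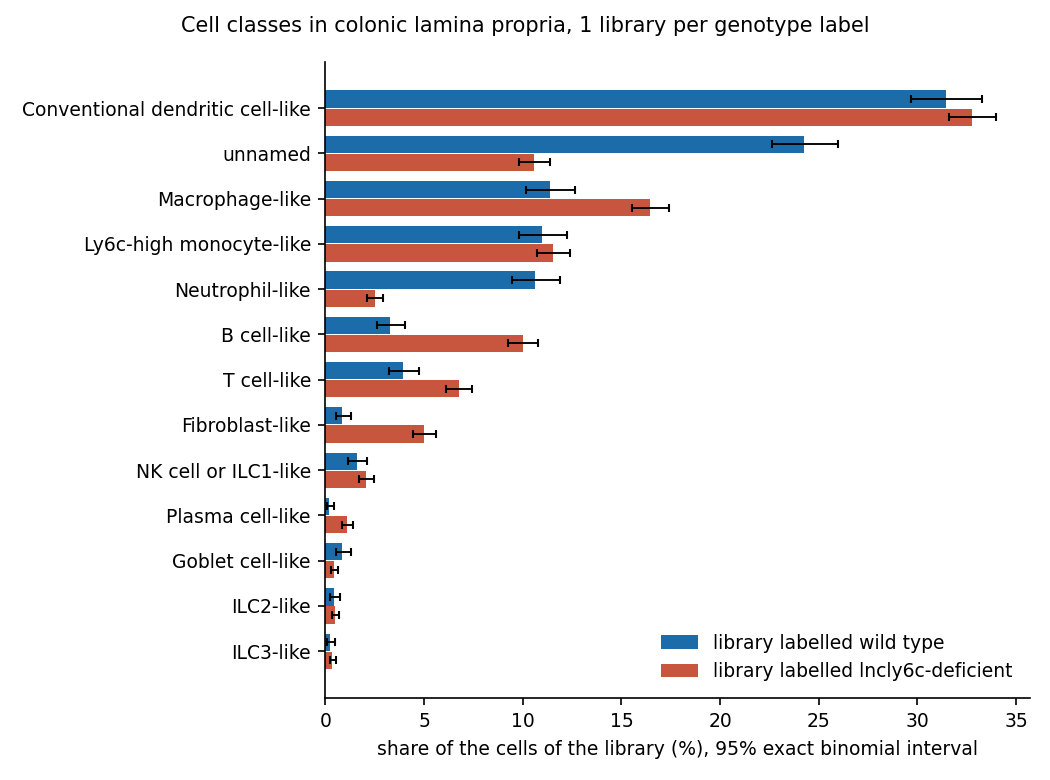
Share of each cell class among the cells of each library, in percent (bars), with 95% exact binomial intervals (lines). Neutrophil-like cells were 10.6% of the wild-type-labelled and 2.5% of the deficient-labelled library, and macrophage-like cells 11.4% and 16.5%.

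The step from Ly6C-high monocytes to Ly6C-low macrophages, which the series title asks about, was read from the balance of these classes. Ly6c-high monocyte-like cells made up 49.1% (45.0 to 53.3) of the 582 monocyte-like and macrophage-like cells of the wild-type-labelled library and 41.2% (38.8 to 43.7) of the 1649 of the deficient-labelled library. Cluster 0, which held most monocyte-like cells, did not differ, at 34.7% (30.8 to 38.7) and 35.5% (33.2 to 37.8). The gap lay in the small monocyte-like clusters 21, at 7.22% and 3.88%, and 23, at 7.22% and 1.88%. The wild-type-labelled library had the larger monocyte-like share of both classes in all 9 settings tried, the reported one included. Clusters were named anew wherever the cells or the clustering changed, so the class did not hold the same cells in every setting. With cells clustered without the Ly6C-high monocyte and mature macrophage genes, the shares were 56.2% and 47.1%. The intervals of both libraries overlapped in 6 of the 9 settings, among them the stricter cell filter, with 59.0% (54.4 to 63.4) and 54.2% (51.6 to 56.8), and doublets removed by score rank, with 58.3% (54.3 to 62.2) and 54.1% (51.6 to 56.6). Cells with a UMI of Ly6c2, which encodes the Ly6C antigen, were 29.9% (26.1 to 34.0) and 24.5% (22.4 to 26.6) of the same cells thinned to 1000 UMIs each, with 31 and 35 shallower cells left out. Without thinning the shares were 47.3% and 45.1%, at median depths of 9110 and 7502 UMIs. In B cell-like cells, taken as the free-RNA background, the thinned shares were 1.19% and 0.856%, and the unthinned ones were 3.53% and 3.23% at medians of 4394 and 3527.5 UMIs.

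Within the classes the Ly6c2 shares pointed in opposite directions. Among monocyte-like cells, 56.1% (50.1 to 62.0) had a Ly6c2 UMI after thinning in the wild-type-labelled and 47.4% (43.5 to 51.2) in the deficient-labelled library. Among macrophage-like cells, 2.56% (1.04 to 5.21) had one in the wild-type-labelled and 6.85% (5.32 to 8.67) in the deficient-labelled library. Thinned shares were 2.97% (0.617 to 8.44) and 5.79% (3.71 to 8.57) in T cell-like cells and 0.620% (0.201 to 1.44) and 1.15% (0.720 to 1.73) in dendritic cell-like cells. The macrophage-like share of the deficient-labelled library lay above the intervals of its B cell-like and dendritic cell-like cells but not of its T cell-like cells, and that of the wild-type-labelled library had an interval that overlapped all of these. The same cluster, number 0 and led by Chil3 and Ly6c2, held most monocyte-like cells of both libraries, 202 of 286 and 585 of 680. Most macrophage-like cells were split between a pair of clusters of about equal size in both libraries. Cluster 5, led by the collagenase gene Mmp13 and by Pf4 and C1qa, held 154 of 296 and 459 of 969 cells, and cluster 4, led by Ptgs2 and Il10, held 141 and 482. Most Ly6c2 UMIs of macrophage-like cells were in cluster 4, with 71 and 630, against 4 and 64 in cluster 5. Cluster 4 was named by a narrow margin, with a score of 0.55 for macrophage and 0.381 for Ly6c-high monocyte markers. No macrophage marker was among its leading genes.

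Gene activity was then compared over all monocyte-like and macrophage-like cells, from 5157851 UMIs of the wild-type-labelled and 13322730 UMIs of the deficient-labelled library. Ly6C-high monocyte genes, inflammatory cytokine and chemokine genes and interferon-stimulated genes were lower in the deficient-labelled library over both classes together. In macrophage-like cells alone the inflammatory median was lower too, at -0.49, but the Ly6C-high median turned to 0.31 and the interferon-stimulated one was -0.01. The summed interferon-stimulated list was lower there all the same, at 1436 and 1070 CPM, with 4 members over 1.5-fold lower and 1 higher. Genes for antigen presentation on MHC class II were higher over both classes together. Their median was 0.80 in monocyte-like cells alone, but in macrophage-like cells alone it was 0.06, at percentile 64.46 of random lists. Genes of mature gut macrophages were higher over both classes together, at a median log2 ratio of 0.26, but not within macrophage-like cells alone, at -0.00, or with both classes weighted equally, at -0.02. Among the genes of the axis named in the series title, Nr4a1 was lower at a log2 ratio of -0.44, though at -0.14 with an interval that reached 0.02 in macrophage-like cells alone, and Cebpb was higher at 0.31. Nr4a1 was also lower in classes outside these cells, such as neutrophil-like and B cell-like cells. All log2 ratios are of CPM, deficient-labelled over wild-type-labelled, with 95% counting intervals in parentheses.

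Nr4a1, an orphan nuclear receptor gene needed for Ly6C-low monocytes, had 235 CPM in the wild-type-labelled and 174 CPM in the deficient-labelled library (log2 ratio -0.44, -0.54 to -0.34). Nr4a1 was at -0.56 (-0.70 to -0.42) in monocyte-like cells alone and at -0.14 (-0.30 to 0.02) in macrophage-like cells alone. It was lower too in neutrophil-like cells, at 609 and 344 CPM, and in B cell-like cells, at 830 and 528 CPM. Every dendritic cell-like and T cell-like cluster also had it lower. It was higher in the fibroblast-like and plasma cell-like clusters and in the unnamed clusters other than the Ace-led one. The lower value was thus not particular to monocyte-like cells. Cebpb, a C/EBP transcription factor gene, had 1338 and 1658 CPM (0.31, 0.27 to 0.35). The list of 16 measured Ly6C-low monocyte and Nr4a1 axis genes had a median log2 ratio of -0.05, at percentile 22.97 of 10000 random lists of the same size and expression. This value leaves out the unnamed Retnla and Ace clusters, and with both counted the median was -0.41. Of its members, 15 lay within 1.5-fold, and 1 was lower by more, the transcription factor gene Klf4 at -0.60 (-0.67 to -0.52). Nr4a2, a close relative of Nr4a1, was at -0.44 (-0.54 to -0.35) and Ace at -0.40 (-0.65 to -0.14). In macrophage-like cells alone Ace was at 0.28.

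Ly6C-high monocyte genes had a median of -0.52 over 14 measured members, below all of the random lists (percentile 0). Among them 6 were over 1.5-fold lower in the deficient-labelled library, 1 was over 1.5-fold higher and 7 lay within 1.5-fold. Most of these genes were also markers that named the monocyte-like clusters. The median and percentile over both classes are therefore not separate from the monocyte-like share. Ly6c2 had 673 and 441 CPM (-0.61, -0.67 to -0.55), and Ccr2, the chemokine receptor gene that monocytes need to leave bone marrow, had 482 and 278 CPM (-0.79, -0.87 to -0.72). The haptoglobin gene Hp was at -0.99 (-1.11 to -0.87) and the fibronectin gene Fn1 at -0.77 (-0.84 to -0.71). In macrophage-like cells alone the list median was 0.31, with Ly6c2 at 1.56 (1.21 to 1.92), and in monocyte-like cells alone it was -0.40. With both classes weighted equally, which removes the difference in monocyte-like share, it was -0.30.

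Of 23 measured mature gut macrophage genes, 6 were over 1.5-fold higher, 1 was over 1.5-fold lower and 16 lay within 1.5-fold, at percentile 99.97. Several of them, such as C1qa and Apoe, were also markers that named the macrophage-like clusters, so this percentile is not separate from the macrophage-like share. The scavenger receptor gene Cd163 was at 1.53 (1.08 to 2.0), the secreted nuclease gene Dnase1l3 at 1.14 (1.02 to 1.27), the hyaluronan receptor gene Lyve1 at 1.03 (0.66 to 1.41) and the acid phosphatase gene Acp5 at 1.0 (0.90 to 1.10). Without macrophage-like cluster 27, which held 1 cell of the wild-type-labelled and 28 of the deficient-labelled library, the list median was 0.10, with Dnase1l3 at 0.73 and Acp5 at 0.62. The median was 0.14 with the stricter cell filter and 0.07 as a mean over cells. Dnase1l3 was at -0.06 in monocyte-like cells alone, and Cd163 was at 0.52 with the stricter cell filter. Cx3cr1, the fractalkine receptor gene and the member that was lower, had 201 and 104 CPM (-0.96, -1.07 to -0.84). Adgre1, which encodes the macrophage antigen F4/80, had 171 CPM in both libraries (0.00, -0.11 to 0.12), and its sign differed between settings.

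MHC class II genes had a median of 0.36 over 10 measured members, above all of the random lists (percentile 100), with 1 over 1.5-fold higher and 9 within 1.5-fold. H2-Ab1, an MHC class II chain gene, had 4521 and 5917 CPM (0.39, 0.37 to 0.41), H2-Ob was at 0.59 (0.26 to 0.94), H2-DMb2 at 0.55 (0.33 to 0.78), H2-Aa at 0.46 (0.44 to 0.48) and H2-Eb1 at 0.43 (0.41 to 0.46). The list median was 0.80 in monocyte-like cells alone, with the list sum at 5745 and 10267 CPM, and 0.06 in macrophage-like cells alone. The same list was also higher in the deficient-labelled library in neutrophil-like cells, at 1754 and 7565 CPM summed, and in T cell-like cells without their deepest cluster, at 884 and 3160 CPM. Droplets also take up free RNA, so these differences cannot be read as expression by the cells alone. MHC class I genes had a median of -0.05 over 10 members (percentile 25.45), with 1 over 1.5-fold higher, H2-Q7 at 1.09 (0.95 to 1.23), and 9 within 1.5-fold.

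Inflammatory cytokine and chemokine genes had a median of -0.60 over 19 measured members (percentile 0), with 10 over 1.5-fold lower, 0 higher and 9 within 1.5-fold. The monocyte-attracting chemokine genes Ccl2, at -1.68 (-1.75 to -1.62), and Ccl12, at -1.43 (-1.61 to -1.25), were among them, as were the interferon-induced chemokine gene Cxcl10 at -1.48 (-1.54 to -1.42) and the interleukin 23 subunit gene Il23a at -1.46 (-1.66 to -1.27). The list was lower in monocyte-like cells alone, at -0.92, and in macrophage-like cells alone, at -0.49. Regulatory and alternative activation genes had a median of 0.05 over 14 members (percentile 65.12), with 2 higher, 2 lower and 10 within 1.5-fold, and a mean of -0.30, with the arginase gene Arg1 lowest. The anti-inflammatory cytokine gene Il10 was at 0.78 (0.72 to 0.83), the chemokine gene Ccl8 at 1.73 (1.01 to 2.55) and the growth factor gene Igf1 at -0.79 (-1.12 to -0.46).

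Interferon-stimulated genes had a median of -0.88 over 15 measured members (percentile 0), with 9 over 1.5-fold lower, 0 higher and 6 within 1.5-fold. Ifit2 was at -1.92 (-2.20 to -1.63), Ifit1 at -1.79 (-2.03 to -1.56), Ifit3 at -1.72 (-2.10 to -1.35) and Usp18, which restrains interferon signalling, at -1.48 (-1.86 to -1.10). The interferon beta gene Ifnb1 was at -2.41 (-2.64 to -2.18), with 488 UMIs in the wild-type-labelled and 237 UMIs in the deficient-labelled library. A small monocyte-like cluster, number 23 and led by Arg1, Rsad2, Ccl2 and Irf7, held 42 cells of the wild-type-labelled and 31 of the deficient-labelled library, or 7.22% and 1.88% of the monocyte-like and macrophage-like cells. Without that cluster the list median was -0.40, with Ifit1 at -1.02, Ifit3 at -0.76, Usp18 at -0.55 and Ccl2 at -1.0, and in macrophage-like cells alone it was -0.01. The macrophage-like list had a mean of -0.31, with 4 of 14 members over 1.5-fold lower, 1 higher and 9 within 1.5-fold. Immediate-early and dissociation genes, which tissue digestion can induce, had a median of -0.24 over 17 members (percentile 0.09), with 3 lower and 14 within 1.5-fold. Among these, Egr1 was at -1.06 (-1.14 to -0.97), Fos at -0.72 (-0.78 to -0.66), Fosb at -0.61 (-0.68 to -0.55) and Atf3 at -0.54 (-0.61 to -0.47).

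Lowest and highest genes here and in the other classes are among genes with at least 100 UMIs, leaving out immunoglobulin and T cell receptor, mitochondrial, ribosomal protein and unnamed predicted genes. The lowest such ratio in these cells was that of Arg1, at -6.37 (-7.39 to -5.52), from 353 UMIs against 11. Of the 353, 294 came from 21 cells of cluster 23, and without that cluster the ratio was -3.98. A further 51 came from 7 cells of cluster 4, 32 of them from 1 cell, so that ratio rests on few cells. The other lowest genes were Slfn4 at -2.82, Terf2ip at -2.34, AA467197 at -1.87, the mitochondrial nucleotide kinase gene Cmpk2 at -1.77 and Fry at -1.69, besides Ifnb1 and the Ifit genes. Terf2ip, which encodes a telomere protein, was at 0.40 in macrophage-like cells alone, and Slfn4, AA467197 and Cmpk2 were at -1.50, -0.83 and -0.96 without cluster 23.

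With immunoglobulin genes left out, the highest ratio was that of Ltbp4, a matrix protein gene also among the leading genes of a fibroblast-like cluster, at 4.14 (2.57 to 6.44) from 3 UMIs against 137. The lysozyme gene Lyz1 followed at 3.75 (3.50 to 4.02), then Gimap6 at 3.10, the secreted phospholipase gene Pla2g2d at 2.92, the secreted protease gene Htra1 at 2.77, the goblet cell gene Agr2 at 2.65, Il22ra2, which encodes a decoy receptor of interleukin 22, at 2.56, Gpm6b at 2.39, Mpp7 at 2.16 and Cst7 at 2.08. Il22ra2, Lyz1 and Dnase1l3 led macrophage-like cluster 27, and without that cluster Lyz1 was at 2.0, Il22ra2 at 1.80 and Pla2g2d at -0.36. Single cells weighed on the remaining Lyz1 counts. They gave 307 of the 585 UMIs of cluster 5 in the deficient-labelled library and 48 of the 62 of cluster 4 in the wild-type-labelled library. As a mean over cells, Ltbp4 was at 2.69, Lyz1 at 2.41, Gpm6b at 0.76 and Pla2g2d at 0.02. With the stricter cell filter Agr2 was at 1.56.

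**Figure D2:**
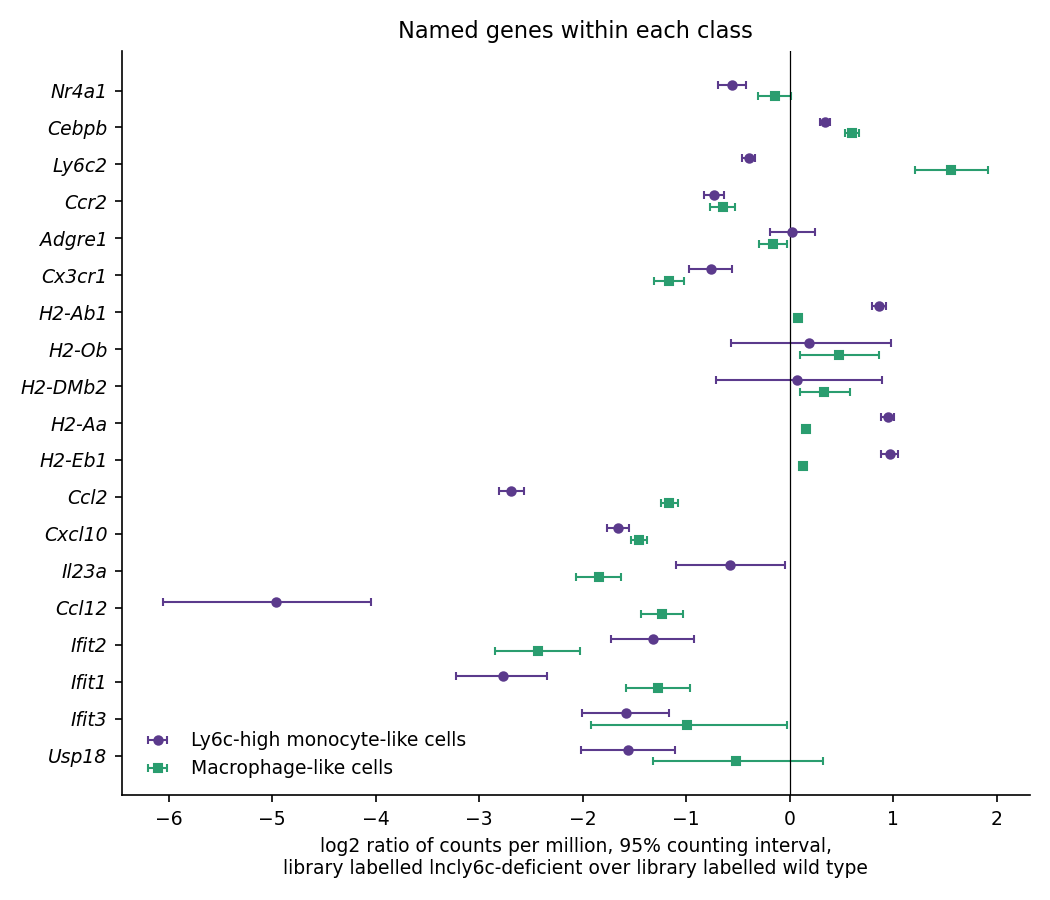
Log2 ratio of CPM, deficient-labelled over wild-type-labelled library, of single genes within Ly6c-high monocyte-like cells (circles) and macrophage-like cells (squares), with 95% counting intervals as lines. Ly6c2 lay at -0.39 in monocyte-like and 1.56 in macrophage-like cells, and Ccl2 at -2.69 and -1.16.

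Glycolysis, respiration and lysosome genes mostly lay within 1.5-fold. All 14 glycolysis genes (median 0.02, percentile 56.31), all 15 oxidative phosphorylation genes (-0.07, percentile 16.685) and all 11 mitochondrially encoded genes (-0.11, percentile 8.645) did so, although the last list was at -0.27 (percentile 0.08) in macrophage-like cells alone, with 10 of 11 members within 1.5-fold. The median of the 17 lysosome and phagocytosis genes was 0.06 (percentile 77.375), with Lyz1 the 1 member over 1.5-fold higher and 16 within 1.5-fold. The 6 measured butyrate receptor and transport genes had a median of -0.04 (percentile 32.17), with 2 higher, 1 lower and 3 within 1.5-fold. In that list the butyrate and niacin receptor gene Hcar2 was at -1.19 (-1.40 to -0.98), the monocarboxylate exporter gene Slc16a3 at 0.88 (0.74 to 1.03) and the histone deacetylase gene Hdac3 at 0.63 (0.12 to 1.17). The 11 measured proliferation genes had a median of 0.09 (percentile 67.905), with 2 higher, 1 lower and 8 within 1.5-fold, and the 7 T helper and cytotoxic genes 0.12 (percentile 74.74), with 3 higher, 1 lower and 3 within 1.5-fold. The sign of the glycolysis, lysosome, butyrate, MHC class I, regulatory, Nr4a1 axis, proliferation and T helper medians differed between settings.

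Genes of other cell types were taken as possible markers of free RNA or adhering cells, and their source was not tested. Immunoglobulin genes had a median of 3.51 over 6 measured members (percentile 100), with 5 higher and 1 within 1.5-fold, led by Igha at 4.66 (4.33 to 5.01), Igkc at 4.47 (4.19 to 4.76), Iglc1 at 3.62 (2.23 to 5.52) and Jchain at 3.41 (2.90 to 3.96). Igha was found in 10.8% of the monocyte-like and macrophage-like cells of the wild-type-labelled and 83.0% of those of the deficient-labelled library. Stromal matrix genes had a median of 1.15 over 9 members (percentile 100), with 7 higher and 2 within 1.5-fold, among them Igfbp7 at 1.84, Mgp at 1.63, Dcn at 1.42 and Col3a1 at 1.34. B cell maturation genes, which share Igha and Jchain with the first list, had a median of 0.42 over 11 members (percentile 99.98), with 4 higher, 1 lower and 6 within 1.5-fold. Epithelial secreted and antimicrobial genes had a median of -0.47 over 5 members (percentile 2.905), with 1 higher, 1 lower and 3 within 1.5-fold, and 0.05 in macrophage-like cells alone. Of the erythrocyte genes 1 was measured, the beta globin gene Hbb-bs at 2.33 (1.04 to 4.00).

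**Figure D3:**
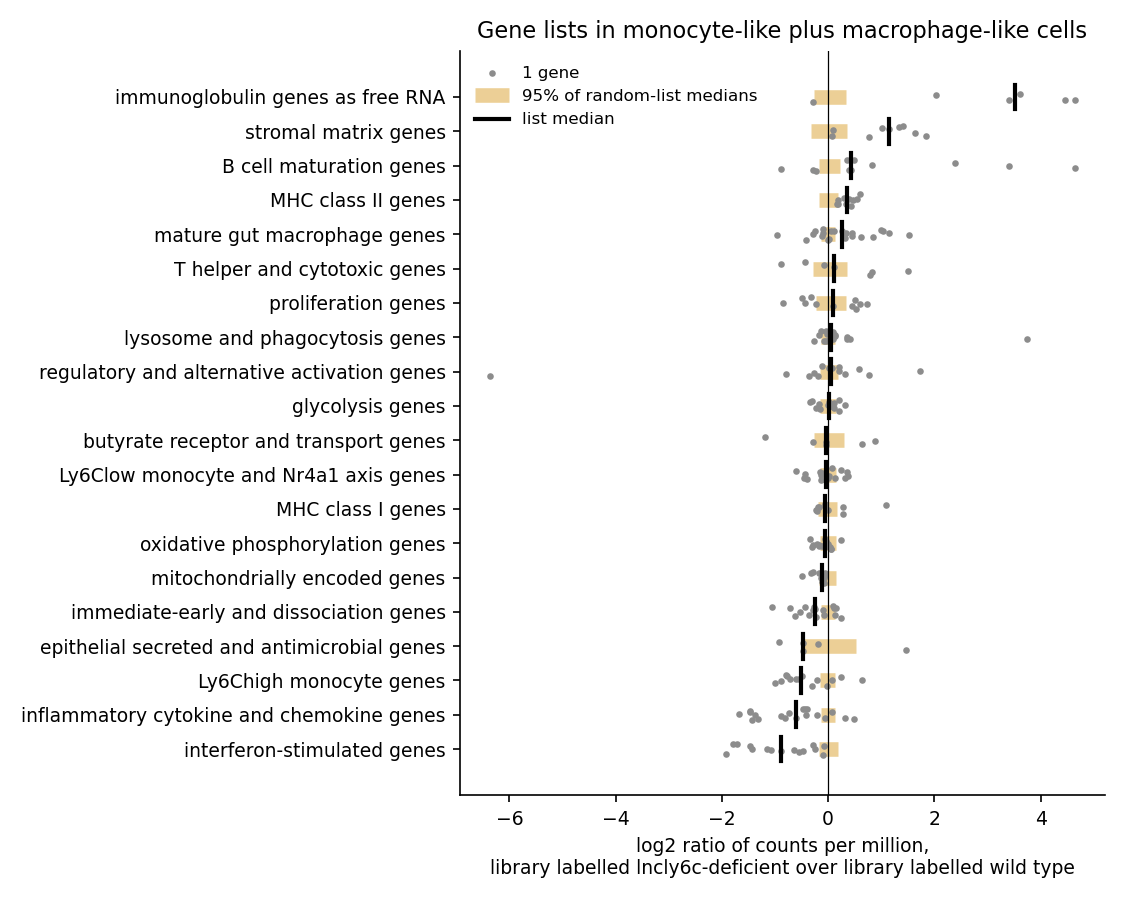
Log2 ratio of CPM, deficient-labelled over wild-type-labelled library, of each list member (points) in monocyte-like and macrophage-like cells, with list medians (lines) and the middle 95% of medians of matched random lists (bands). The interferon-stimulated median lay lowest at -0.88 and the immunoglobulin median highest at 3.51.

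Monocyte-like and macrophage-like cells were also compared apart, 286 and 680 cells in the former and 296 and 969 in the latter. In monocyte-like cells Ccl12 was at -4.96 (-6.05 to -4.04) and Ccl7, another monocyte-attracting chemokine gene, at -4.38 (-4.74 to -4.04), while Arg1 was at -9.23 (-14.54 to -6.74) from 301 UMIs against 1. Cluster 23 carried most of these UMIs in the wild-type-labelled library, 154 of 156 for Ccl12, 739 of 791 for Ccl7 and 294 of 301 for Arg1. Lyz1 at 3.30, the alternative activation gene Retnla at 2.90 and Fkbp5, a glucocorticoid target gene, at 2.13 were highest once immunoglobulin genes, with Igha at 4.25, Igkc at 4.32 and Jchain at 3.92, were left out. In macrophage-like cells Fry at -2.58, Ifit2 at -2.43 and Ifnb1 at -2.26 were lowest, and Lyz1 at 3.58, Ltbp4 at 3.43 (1.84 to 5.73, from 3 UMIs against 102) and Gimap6 at 3.16 were highest after Igha at 4.74 and Igkc at 4.42, which the rule leaves out. Of the 3938 Lyz1 UMIs of the deficient-labelled library, 3147 came from the 28 cells of cluster 27. Cx3cr1 was at -1.16, Il23a at -1.84 and the chemokine gene Ccl4 at -1.60 in macrophage-like cells, and Thbs1 was at 1.26.

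Conventional dendritic cell-like cells, 819 and 1930 cells, had lower inflammatory and interferon-stimulated genes in the deficient-labelled library as well. The values are over the whole class, of which cluster 7 was a larger share of the deficient-labelled library. Interferon-stimulated genes had a median of -0.60 over 15 members (percentile 0), with 8 over 1.5-fold lower and 0 higher, and Ifit1 was at -2.34 (-2.56 to -2.13). Inflammatory cytokine and chemokine genes had a median of -0.38 over 18 members (percentile 0), with 8 lower and 2 higher, and Ccl4 was at -2.12 (-2.18 to -2.06). The sum of that list was nearly equal, at 4049 and 3908 CPM. Ifnb1 was at -3.12 (-3.60 to -2.66). Cd207, which encodes the lectin langerin, at 4.05 (3.26 to 4.97), Gimap6 at 3.28 and Ltbp4 at 2.97 were highest with Igkc at 4.13 and Igha at 3.83 left out, and MHC class II genes had a median of -0.02.

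Neutrophil-like cells, 277 and 147 cells, had a median of 2.27 over 5 measured MHC class II genes, all over 1.5-fold higher in the deficient-labelled library, with H2-Ab1 at 2.52 (2.30 to 2.74), H2-Eb1 at 2.27 and H2-Aa at 2.27. Free RNA was not separated from expression in these shallow cells, in which Igkc was also higher, at 5.10 (4.44 to 5.83). Their immediate-early genes had a median of -0.50 over 17 members (percentile 0) and their interferon-stimulated genes -0.39 over 10 members. The acute-phase gene Saa3 at -1.60, Ifit3 at -1.60 and the activin gene Inhba at -1.59 were lowest, and Hcar2 was at -0.86 (-1.01 to -0.72).

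T cell-like cells, 102 and 398 cells, came from the same clusters in both libraries, but in different proportions. Cluster 13, led by Cd3g and Trbc2, held most of those of the wild-type-labelled library, 56 of 102, while cluster 15, led by Ctla4, Cd28 and Icos, was the largest in the deficient-labelled library with 162 of 398 cells, against 15 in the other. Cluster 15 had a median of 14403 UMIs per cell and 29.4% of its cells were among those removed by doublet score rank. It also held H2-Ab1 at 7312 CPM and 549 of the 550 Il12b UMIs of the class in the deficient-labelled library. In the class Apol7c was at least 3.29 higher on the log2 scale (0 UMIs against 153), Il12b, an interleukin 12 subunit gene of antigen-presenting cells, was at 6.72 (4.23 to 12.02) from 1 UMI, and Gzma, a cytotoxic granule protease gene, was at 4.94 (3.07 to 7.99) from 2 UMIs. Spry2 at -2.76, Mid1 at -2.41 and Tsc22d1 at -1.95 were lowest. MHC class II genes had a median of 1.32 over 10 members, and 1.84 over 5 members without cluster 15, and Ly6C-high monocyte genes had 1.18 over 12 members and 0.15 over 5 without it. Inflammatory cytokine and chemokine genes, lower in monocyte-like and macrophage-like cells, were higher here, at 1.17 over 18 members (percentile 100), with 12 over 1.5-fold higher, and at 1.72 over 6 members without cluster 15.

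A few genes stood on the same side in every class. Among 2600 genes with at least 50 UMIs in each of the 5 classes compared, 3 were at least 2-fold higher in the deficient-labelled library in every class and 4 at least 2-fold lower. These genes were chosen after their values were seen. Igha had log2 ratios of 3.83 to 4.74, Igkc of 3.69 to 5.10 and Mpp7 of 1.78 to 2.38. On the other side were AY036118 at -1.50 to -1.07, Gm42418 at -1.65 to -1.03, Lars2 at -1.45 to -1.17 and the ubiquitin ligase gene Mid1 at -2.41 to -1.60.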

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

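The score-rank removal of doublets, the inclusion of the unnamed Retnla and Ace clusters, the equal weighting of classes, the settings without cluster 23 or 27, and all settings for single genes were chosen only after the result was seen. Against the counting or resampling interval of the reported value, 147 shares stayed inside it and 47 did not. Among list medians 265 stayed inside, 10 moved out and 1 reversed, and among single genes 459, 145 and 5. The interval of a list median is wide, so staying inside it is a weak check. The library with the larger share was the same in every setting for each class but the Ly6c-high monocyte-like one. Clusters were named anew wherever the cells or the clustering changed, so a class can hold other cells there than in the reported setting. Values outside are given as wild-type-labelled, then deficient-labelled, and the cause was not tested unless stated.

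The stricter cell filter gave ILC3-like shares of 0.567% and 0.750%, Ly6c-high monocyte-like shares of 13.4% and 14.7% (59.0% and 54.2% of monocyte-like plus macrophage-like cells), macrophage-like shares of 9.31% and 12.4%, a neutrophil-like share of 12.3% in the wild-type-labelled library and a mitochondrial list median of -0.044. That list's value can follow from the lower mitochondrial limit of the filter. With doublets kept, dendritic cell-like cells were 34.2% of the deficient-labelled library. Removal by score rank gave 35.1% for these, monocyte-like shares of 14.1% and 15.2% (58.3% and 54.1% of both classes), macrophage-like shares of 10.1% and 12.9% and an Nr4a1 axis median of -0.15.

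At resolution 0.5, dendritic cell-like shares were 28.5% and 30.2%, monocyte-like shares 14.3% and 14.8% (58.6% and 52.7%) and macrophage-like shares 10.1% and 13.3%. At resolution 2, dendritic cell-like shares were 24.7% and 27.1%, and the deficient-labelled library had 12.9% macrophage-like cells and 46.4% monocyte-like cells of both classes. Genes centred within libraries gave dendritic cell-like shares of 33.4% and 35.4%, monocyte-like shares of 14.1% and 15.05% (57.9% and 53.7%) and a deficient-labelled macrophage-like share of 12.99%. Clustering without the list genes gave monocyte-like shares of 13.7% and 13.4% (56.2% and 47.1%) and a deficient-labelled macrophage-like share of 15.1%.

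With the unnamed Retnla and Ace clusters as macrophage-like, monocyte-like cells were 41.0% and 36.2% of both classes, and the Nr4a1 axis median was -0.41. Ly6c2 was found in 47.3% and 45.1% of cells without thinning and in 39.9% and 32.7% at 2000 UMIs, as more UMIs per cell give more cells with one. In macrophage-like cells alone, the Ly6C-high median reversed to 0.31, the MHC class II median was 0.061 and the interferon-stimulated median -0.014, and Ace (0.28), Ly6c2 (1.56) and Terf2ip (0.40) reversed. In monocyte-like cells alone the MHC class II median was 0.80, the mitochondrial one -0.069 and the regulatory one 0.34, and Dnase1l3 reversed to -0.058. With equal weights the MHC class II median was 0.17. Without cluster 23 the interferon-stimulated median was -0.40, and without cluster 27 Pla2g2d reversed to -0.36, since most of its UMIs came from that cluster.

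The deleted gene had 0 UMIs also over all barcodes, and why was not tested. Depth limits the ratios of genes with few UMIs in the wild-type-labelled library, such as Ltbp4 with 3.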

Other observations

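The tests of dilution by other cells and of exchanged labels, and the medians over a fixed set of interferon-stimulated genes, were chosen only after the result was seen. Beyond the genes described above, the heat shock protein genes Hspa1a and Hspa1b were at log2 ratios of 1.20 (1.15 to 1.25) and 0.75 in conventional dendritic cell-like cells, whose immediate-early and dissociation list, which holds both, had a median of -0.08 with 2 of 17 members over 1.5-fold higher. The hexokinase gene Hk2 was at -0.98 (-1.04 to -0.92) and the transcription factor gene Ikzf2 at -1.39 (-1.65 to -1.13) in the same cells, while C1qb was at 1.30, Fn1 at 1.10 and the lysozyme gene Lyz2 at 0.95. In monocyte-like cells the coagulation factor gene F13a1 was at -0.85 (-0.98 to -0.72), Hcar2 at -1.48 (-1.75 to -1.21) and Slc16a3 at 1.02 (0.86 to 1.18). Their immediate-early gene Fosb was at -1.38 and their complement gene C1qb at 1.54.

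Igha was found in more than 54% of the cells of every class of the deficient-labelled library. Its monocyte-like and macrophage-like cells had 5.51 (5.12 to 5.92) Igha UMIs per Jchain UMI, its dendritic cell-like cells 5.77 (5.37 to 6.20), its T cell-like cells 5.66 (4.81 to 6.71) and its B cell-like cells 4.23 (3.59 to 5.02). Its plasma cell-like cells had 2.25 (2.23 to 2.27), below each of these intervals, and the source of these transcripts was not tested. In the wild-type-labelled library plasma cell-like cells had 3.15 (3.07 to 3.24), dendritic cell-like cells 2.95 (2.19 to 4.02), and monocyte-like and macrophage-like cells 2.31 (1.51 to 3.62).

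Neutrophil-like cells were 10.6% of the wild-type-labelled and 2.5% of the deficient-labelled library. Loss of shallow cells from the deficient-labelled library would bring the shares together among deep cells. Among cells with at least 2000 UMIs the ratio was 6.72 (5.34 to 8.45), with 12.5% against 1.86%. Median depths of neutrophil-like cells were 3024 and 2276 UMIs, and this limit kept 248 of 277 and 97 of 147 of them. Because the limit itself took out more of the deficient-labelled ones, the test cannot decide on loss of shallow cells. Dilution by lymphoid and stromal cells was argued against as the whole cause by the ratio per monocyte-like, macrophage-like and dendritic cell-like cell, at 4.81 (3.90 to 5.93). A difference in tissue handling or recovery, between animals, or between genotypes may account for the pattern, and with 1 library per group none of these was tested.

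Interferon-stimulated genes were lower in monocyte-like cells of the deficient-labelled library, at a median of -0.79 over 15 genes. In macrophage-like cells their median was -0.01, with a sum of 1436 and 1070 CPM. Free RNA in the wild-type-labelled library would raise these genes in B cell-like cells too, and was argued against, as the difference in B cell-like cells was -0.0419 (-0.0820 to 0.0026) of that in monocyte-like cells, with 175 and 222 CPM against 2689 and 1566 CPM summed. A different number of cells in cluster 23 may be part of the pattern, since outside it the median was -0.26 (-0.30 to -0.02) over the 11 genes still measured, which had -0.50 in all monocyte-like cells, and -0.29 (-0.51 to -0.16) over all 15, and both intervals span the -0.2 set as the limit. The summed list had 13080 and 7937 CPM in cluster 23, 1430 and 1233 in cluster 0 and 1289 and 1226 in cluster 21, and in macrophage-like cells 993 and 774 in cluster 4, 1892 and 1279 in cluster 5 and 1189 and 1540 in cluster 27. Monocyte-like cells outside cluster 23 thus had the list lower too, but by less. How much of the pattern that cluster carries cannot be told from these values. The list was lower also in dendritic cell-like cells, at a median of -0.60, and in neutrophil-like cells, at -0.39. In T cell-like cells it was at 0.22. An effect of the deletion stays open and untested.

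Every direction between the libraries rests on the labels, and the labels and the file names disagree. With the genotype labels of both libraries exchanged, lncly6c UMIs would be seen in the deficient-labelled library alone, but there were 0 UMIs over both libraries. Correct and exchanged labels therefore cannot be told apart from the deleted gene, because it was not detected in either.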
